A study of Rattus norvegicus with 8 samples.

How the data were processed

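Hypothalamic total RNA of 4 female rats in estrus and 4 males, Sprague Dawley, 3 to 4 months old, was measured on 4 two-colour Agilent arrays of 1 slide, with added spike-in RNA. Each array held 1 female and 1 male, as the labels and the identical contents of the paired files show, and the dye of each sample was taken from the labels. Per the submitters' processing notes, scans were quantified with Agilent Feature Extraction 10.7.3.1. Per the file headers, the spot and local background signals of each channel are intensity values as scanned, and the processed signals are intensity values after the scanner software's background subtraction, detrending and dye normalization. Per the file headers, the log ratio is the log10 of red over green processed signal. The value table deposited by the authors holds log2 values, equal to the log2 of median signal minus median local background less 1 constant per column, within 0.01 for 100% of the 27946 to 30846 values of each sample. The median of each of its 8 columns was 0, so scale and centring are settled, and columns of other samples numbered 0. Lone carriage returns inside lines of the files of array 4 were read as line ends.

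Each array carried 44254 features, of which 1377 were controls. The 42877 others held 30367 unique probes, 1390 of them on several spots. Names came from accessions matched to current reference names for 17328 probes and from the array files for 5371, and 7668 had no gene name. Probe positions were those of the array files on the rn4 build. By position 1244 probes were X-linked, 0 Y-linked, and 1406 had no position.

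Mean signals were corrected with normexp against the median local background (offset 50) and normalized by loess within arrays, with controls at weight 0, in limma 3.58.1 under R 4.3.3, with the packages data.table (1.17.8) and jsonlite (2.0.0). Outlier spots, 931 to 1096 per array, were left out and spots of a probe averaged. A probe was kept if over 0.5 of its spots were well above background in all 4 samples of at least 1 sex, and 21995 of the 22004 probes that passed could be fitted with at least 1 residual degree of freedom. The log2 ratio of female over male was fitted with limma (lmFit, eBayes) with a term for sex and a gene-specific term for dye. Adjusted p-values are Benjamini-Hochberg over probes with a threshold of 0.05, and for cytoskeletal genes also adjusted over the list alone. A gene was represented by its brightest probe, which gave 14603 genes. Median signal above background was 502 to 530 in Cy3 and 148 to 272 in Cy5, and the number of arrays limits precision.

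The pairing comes from the array that each female and male shared, which is the block of the fit, since each ratio is taken within 1 array. As a check, the deviations of the 2 animals of an array from their sex's mean correlated across genes at 0.61, 0.68, 0.46 and -0.08 for arrays 1 to 4; genes are not independent replicates.

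Lists were tested at gene level with limma's camera at a preset correlation of 0.01, with an estimated correlation and fry as alternatives, and Benjamini-Hochberg over 33 lists with at least 3 complete members. They were 10 cytoskeletal lists (among them actin, tubulins and microtubule-associated proteins, intermediate filaments, myosins, kinesins, cytoplasmic dynein and dynactin, cilia and axoneme, septins, spectrins and ankyrins), 2 adhesion lists, sex chromosome lists, endocrine lists, circadian, immediate early and stress lists, cell type and neighbouring tissue markers, ribosomal proteins, oxidative phosphorylation and all X-linked genes. Y-linked genes, with 2 measured members, were reported gene by gene. Spread between animals was the median over genes of the log2 ratio of female to male standard deviation, after removal of the dye effect, with two-sided exact permutations over 35 splits of the animals and 8 exchanges within arrays.

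Genes were named by a rule. In each direction it took up to 10 genes past the threshold with the largest change and 1 sign on all arrays, or the 5 with the smallest p where fewer than 5 passed. It added the measured Y-linked genes, the X-linked genes with a Y-linked partner, and up to 3 members of each other list with the smallest p. It gave 108 genes. These lists, the rule, the tests described so far and the alternatives were fixed before the data were examined. Tests and a gene list chosen later are marked as such where they are reported.

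Alternatives were no dye term, a separate-channel fit without the array as block, no background correction, normexp offset 16, median centring, the scanner software's log ratio, the authors' value table, no filter on dim probes, all channels well above background, outlier spots kept, saturated spots left out, the mean of a gene's probes, an intensity trend with a robust prior, a threshold of unadjusted p with 1.5-fold, and leaving out each replicate. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

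The steps were tested on simulated data of the same size. Of 100 genes changed 2-fold, 82% had an adjusted p under 0.05, with a median log2 ratio of 1.01, and of 100 changed 4-fold, 95% did, with 1.98. Of 188 genes called, 10 were unchanged and 1 belonged to the list moved as a whole. With nothing changed, 0 passed. A list moved as a whole was recovered at 0.29, with an adjusted p of 3.46e-25 at the preset correlation and 0.434 with an estimated correlation, and 0 other lists passed. A simulated ratio of standard deviations of 1.5 came back as 1.26, with an exact permutation p of 0.0286. Probes were simulated as varying independently, while the estimated correlation in the real lists reached 0.67, in meningeal and fibroblast markers. The simulation therefore does not test the list calls at the preset correlation, or the spread test, where genes vary together. It also changed all these genes and a list at once, capped the largest probe variances and gave each array the same noise. Real log2 ratios had a standard deviation of 0.64 on array 2, against 0.38 to 0.39 on arrays 1, 3 and 4. The recovered shares therefore do not say how many 2-fold differences the real arrays would show. Among 10 spike-in RNAs the median absolute log2 ratio between sexes was 0.07 and the largest 0.27, while the largest absolute dye effect was 1.19.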

Results

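Gene expression was measured in the hypothalamus of 4 female Sprague Dawley rats in estrus and 4 males, all 3 to 4 months old. The hypothalamus is the brain region that governs pituitary hormone release, feeding, body temperature and reproductive behaviour. The question was how the sexes differ, above all in genes of the cytoskeleton. The 4 arrays of 1 slide each held the RNA of 1 female and 1 male in opposite dyes, with replicate 1 of both sexes on array 1 and so on. Females carried Cy3 on arrays 1 and 3 and Cy5 on arrays 2 and 4. The median spot signal above local background was 502 to 530 intensity units in the 4 samples labelled with Cy3 and 148 to 272 in the 4 labelled with Cy5. Between 84.9% and 87.0% of 42877 spots were well above background in the Cy3 samples, against 77.6% to 80.2% in the Cy5 samples, and 0 spots were saturated. Precision is limited by the number of arrays. All differences below are log2 ratios of female over male with the standard error of the fit to 4 arrays, and chromosome positions are those of the probe on the rn4 build.

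Towards females, the genes with the smallest p were Sycn, Pdgfrl, Slc47a1, Krt19 and Mrpl18, and none passed the threshold. Sycn, which encodes a protein of secretory granules, had a log2 ratio of 0.60 ± 0.06, above 0 on 4 of 4 arrays (chromosome 1, 83651560 to 83651619). Pdgfrl, related to the receptors of platelet-derived growth factor, reached 0.68 ± 0.07 (chromosome 16, 54666068 to 54666127). Slc47a1, an exporter of organic cations, reached 0.67 ± 0.07 (chromosome 10, 47514303 to 47514362). Both ratios were above 0 on 4 of 4 arrays, as were those of the epithelial keratin gene Krt19, at 0.82 ± 0.10, and of Mrpl18, a mitochondrial ribosomal protein gene, at 0.60 ± 0.08. Mrpl18 varied with the dye, at 0.22 and 0.01 on arrays 1 and 3 and 0.98 and 1.19 on arrays 2 and 4. The size of each gene's ratio depended on the processing. Over the alternatives Sycn ranged from 0.58 to 1.26, Pdgfrl from 0.62 to 0.97 and Slc47a1 from 0.61 to 1.64. Krt19 ranged from 0.70 to 1.59 and Mrpl18 from 0.52 to 0.65.

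Towards males, Ing3, a reader of histone marks, had a log2 ratio of -0.85 ± 0.08 and was below 0 on 4 of 4 arrays (chromosome 4, 48281011 to 48281070). Ing3 varied with the dye, at -1.30 and -1.54 on arrays 1 and 3 and -0.35 and -0.21 on arrays 2 and 4. Retreg3, a regulator of endoplasmic reticulum turnover, stood at -0.82 ± 0.09 and was below 0 on 3 of 4 arrays. Spock3, a brain proteoglycan gene, stood at -0.70 ± 0.10, Tmem255a at -0.46 ± 0.07 and the syntaxin gene Stx7 at -0.42 ± 0.06, each below 0 on 4 of 4 arrays. The smallest p of all probes, 2.02e-04 unadjusted, belonged to a probe without a gene name or position, A_64_P072778, chosen for mention after its values were seen. It read -1.65, -1.31, -1.54 and -2.02 on arrays 1 to 4, with a fitted log2 ratio of -1.63 ± 0.14, and was well above background in all 8 samples.

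Of 21995 probes tested with limma, 0 had an adjusted p under 0.05, and 1870 had an unadjusted p under 0.05. The lowest adjusted p was 0.555, which the 10 genes named above share. Among 14603 named genes the counts were 0 and 1244, of which 731 were higher in females and 513 in males. That split depended on the scaling, with 244 against 533 after median centring, 430 against 616 in the log ratios of the scanner software and 156 against 1013 in the authors' value table. An unadjusted p under 0.05 together with a 1.5-fold difference was met by 132 genes, 53 higher in females and 79 in males. The sign was shared by 4 arrays for 10.5% of genes; 4 independent arrays would give 12.5% by chance, but arrays that share a dye orientation are not independent. Leaving out replicate 4 left array 2 as the only array with females in Cy5, so its ratios entered each estimate unchecked by another array. In that fit 1132 genes passed, 564 higher in females and 568 in males. Among them were 27 of the 108 genes named by rule, with adjusted p from 0.0294 to 0.0494: Dock6, Drd2, Eif2s3, Gal, Ing3, Kif21a, Klf9, Krt19, Lhx2, Mlc1, Moxd1, Mrpl18, Myh11, Neurod6, Nnat, Odf3b, Ogn, Pdgfrl, Ptpn3, RT1-Bb, Retreg3, Rpl10l, Slc47a1, Spock3, Sycn, Tac3 and Tef. The number of genes at an unadjusted p under 0.05 was 600 without replicate 1, 303 without replicate 3, 4546 without replicate 4 and 405 without a term for the dye.

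**Figure D1:**
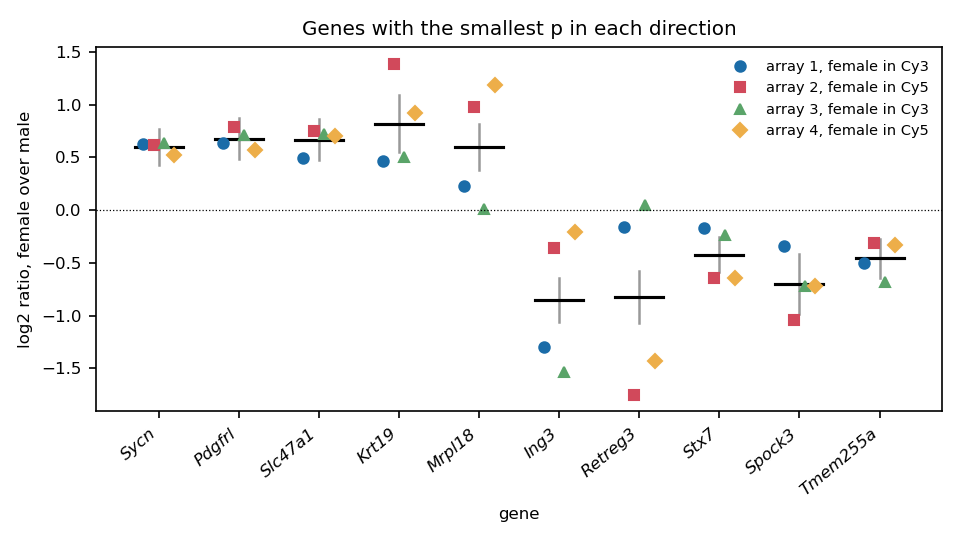
Log2 ratio of female over male (vertical axis) on each of the 4 arrays for the 5 genes with the smallest p in each direction, each gene read from its brightest probe; points are arrays, black lines the fitted ratios and grey lines their 95% confidence intervals. Sycn lies between 0.52 and 0.64 on the 4 arrays, while Retreg3 spreads from -1.75 to 0.05 with the dye.

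Dye moved the ratios more than sex did. A dye effect passed the threshold at 2797 of 21995 probes, and its standard deviation over genes was 0.34 on the log2 scale, against 0.20 for the sex difference. Ratios of arrays with the same dye orientation correlated across genes at 0.66 for arrays 1 and 3 and at 0.47 for arrays 2 and 4, while arrays of opposite orientation correlated between -0.64 and -0.30. Genes are not independent replicates in these correlations. The dye term lowered the median residual variance from 0.0788 to 0.0270, and with 2 arrays per orientation it also takes up part of the differences between animals. Array 2 had the widest spread of log2 ratios, with a standard deviation of 0.64, against 0.38 to 0.39 on the other 3 arrays. For some genes named by rule the sign followed the dye, with 1 sign on arrays 1 and 3 and the other on arrays 2 and 4. They included Eif2s3, Dcx, Dock6, Kif21a, Bicd2, Ndufs7, Tmem212, Tpm2, Myh11, Myo1f, Evpl and Ogn. Others were Nnat, Sult1a1, RT1-Bb, Klf9, Tef, Ncoa3, Uba1 and Med14.

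Among the X-linked genes with a Y-linked partner, the initiation factor gene Eif2s3 had the largest ratio towards females. Its log2 ratio was 0.61 ± 0.09, or 1.52-fold, with 0.63 at its second probe (chromosome X, 81544055 to 81544114). Its ratios were 1.503 and 1.33 on the arrays with females in Cy3 and -0.37 and -0.05 on those with females in Cy5. Ddx3x, an X-linked RNA helicase gene, stood at 0.33 ± 0.07 and was above 0 on 4 of 4 arrays, although its dimmer second probe read -0.15. Eif1ax, another initiation factor gene, stood at -0.67 ± 0.17 and below 0 on 4 of 4 arrays, with 0.00 at its second probe (-0.0036). Ube1y1, a Y-linked gene for a ubiquitin-activating enzyme, was well above background in 4 of 4 males and in 0 of 4 females, with a log2 ratio of -0.42 ± 0.11. Because the female signal was near background, the size of that ratio depended on the processing and ranged from -3.77 to -0.29 over the alternatives.

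The other X-linked genes with a partner on the Y chromosome had ratios between -0.15 and 0 at their brightest probe. They were Uba1 at -0.08 ± 0.06, Usp9x at -0.15 ± 0.22, with -0.39 ± 0.08 and 0.50 ± 1.15 at its other probes, Zfx at -0.06 ± 0.07, Med14 at -0.03 ± 0.06 and Rbmx at -0.07 ± 0.10. The probe of Sry, the testis-determining gene of the Y chromosome, read 0.02 ± 0.07 and was well above background in all 8 samples, females included, so its signal does not tell the sexes apart. With limma, 0 of these 8 X-linked genes passed over all probes, 3 had an unadjusted p under 0.05, and 3 passed when adjusted over the list alone, with 0.0139 as the lowest adjusted p. As a list their median was -0.06 with an adjusted p of 0.812, although fry's test of change in either direction gave 0.0351. The 471 X-linked genes measured had a median of 0.02 and an adjusted p of 0.83. Eif2s3 passed without replicate 4, at 0.53 with an adjusted p of 0.0449.

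**Figure D2:**
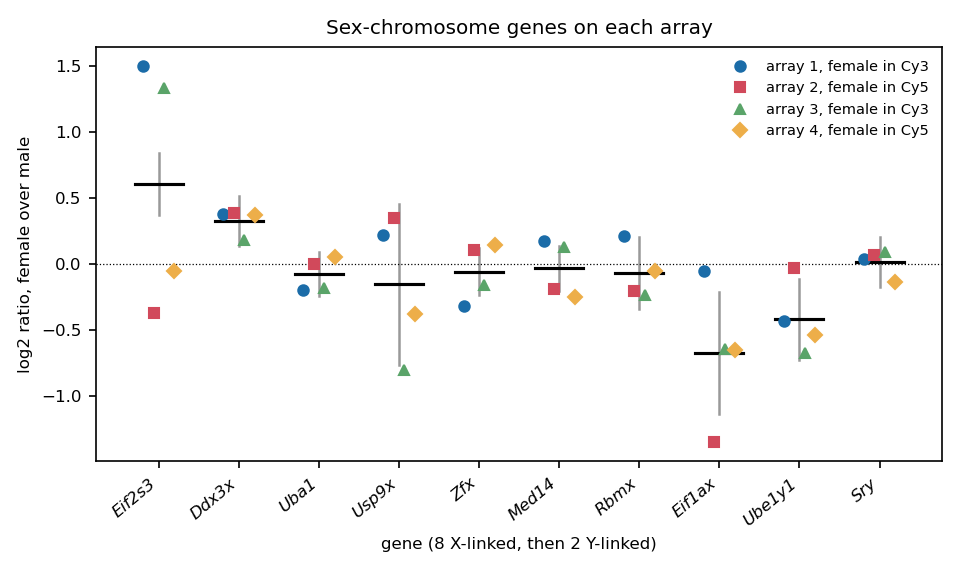
Log2 ratio of female over male (vertical axis) on each of the 4 arrays for 8 X-linked genes with a Y-linked partner and 2 Y-linked genes; points are arrays, black lines the fitted ratios and grey lines their 95% confidence intervals. Eif2s3 is fitted at 0.61, Ddx3x at 0.33 and Ube1y1, not well above background in females, at -0.42.

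Cytoskeletal genes split towards both sexes. In order of p, Krt19 was followed among those higher in females by the neuronal intermediate filament gene Ina, at 0.39 ± 0.06 and above 0 on 4 of 4 arrays (chromosome 1, 252340311 to 252340370). Dock6 stood at 0.41 ± 0.07, and Myh11, the myosin heavy chain of smooth muscle, at 0.62 ± 0.11, both with signs that followed the dye. Lower in females were Eml2, a microtubule-associated protein gene, at -1.30 ± 0.19 and below 0 on the 3 arrays that measured it, and Map1a, a neuronal microtubule-associated protein gene, at -0.40 ± 0.09 and below 0 on 4 of 4 arrays. Arhgef2 and Arhgef11 stood at -0.49 ± 0.11 and -0.30 ± 0.07.

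Of 596 cytoskeletal genes tested with limma, 0 passed over all probes, 0 passed when adjusted over the list alone, where the lowest adjusted p was 0.407, and 69 had an unadjusted p under 0.05. Of these 69, 46 were higher in females and 23 in males, and 11 also differed by 1.5-fold. Without replicate 4, cytoskeletal genes differing between sexes numbered 60 over all probes and 103 when adjusted over the list alone. The number of cytoskeletal genes at an unadjusted p under 0.05 was 32 without replicate 1, 30 without replicate 3, 223 without replicate 4 and 20 without the dye term.

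Cilia and axoneme genes, which build the microtubule core of motile cilia, were higher in females as a list. Of 85 measured, 66 had a ratio above 0, 16 of them at an unadjusted p under 0.05, and the list's median was 0.11. The outer dense fibre gene Odf3b stood at 0.43 ± 0.08 and the axoneme gene Cfap43 at 0.43 ± 0.08, both above 0 on 4 of 4 arrays, and the dynein light chain gene Dynlrb2 at 0.44 ± 0.09. With camera and a preset correlation the list rose with an adjusted p of 2.6e-04. With an estimated correlation its adjusted p was 0.814, but that test also missed the list moved in the simulation, at 0.434. Without replicate 2 the median was 0.07, and male replicate 2 had a median level of -0.30, against -0.05 to 0.04 in the other males. The list shares 6 genes with the ependymal and choroid plexus markers.

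Actin and actin-binding genes shifted by a small amount towards males. Of 127 measured, 78 had a ratio below 0, and the median was -0.05. The actin-monomer-binding genes Pfn1 and Cap1 stood at -0.90 ± 0.22 and -0.87 ± 0.21, while the tropomyosin gene Tpm2 stood at 0.59 ± 0.14. The sign of Tpm2 followed the dye, at -0.18 and -0.90 on arrays 1 and 3 and 1.83 and 1.62 on arrays 2 and 4. The list fell with an adjusted p of 0.0301 at the preset correlation, and its adjusted p was 0.814 with an estimated correlation. The call was lost without replicate 2 (-0.01, adjusted p 0.344), without replicate 3 (-0.02, adjusted p 0.233) and without the filter on dim probes (-0.04, adjusted p 0.0609). Its median was -0.09 without replicate 4, and male replicate 2 had a median level of 0.09, against -0.0095 to 0.01 in the other males.

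Other cytoskeletal lists did not pass. Intermediate filament genes had a median of 0.09 (adjusted p 0.183), with Evpl at 0.26 ± 0.07, and 1 gene, Krt19, passed when adjusted over the list alone, at 0.0355. With median centring the list passed, at 0.09 with an adjusted p of 0.0137. Septins had a median of -0.14 (adjusted p 0.146), with Septin7 at -0.99 ± 0.59, Septin11 at -0.23 ± 0.08 and Sept6 at 0.15 ± 0.08. Without replicate 4 the septins passed, at -0.22 with an adjusted p of 0.0414. Over the alternatives the median of the septins ranged from -0.22 to 0.01. Tubulins and microtubule-associated proteins had a median of -0.01 (adjusted p 0.464), with Dcx at 0.30 ± 0.07. The sign of Dcx followed the dye, and its second probe read -0.0068. Spectrins, ankyrins and the membrane skeleton were at -0.0028 (adjusted p 0.607), with Epb41l4a at 0.20 ± 0.06, Sptb at 0.24 ± 0.08 and Epb41l1 at -0.18 ± 0.07. Myosins were at 0.02 (adjusted p 0.812), with Myo1f at 0.21 ± 0.07 and Myo9b at 0.18 ± 0.06, and 0.15 and -0.10 at the other probes of Myo9b. Kinesins were at 0.0063 (adjusted p 0.914), with Kif21a at 0.44 ± 0.13, Klc4 at 0.28 ± 0.08 and Kif26b at 0.22 ± 0.07. Cytoplasmic dynein and dynactin were at -0.01 (adjusted p 0.812), with Hook3 at 0.30 ± 0.14, Hook2 at 0.25 ± 0.13 and Bicd2 at 0.15 ± 0.06. For kinesins the test pointed down while the median was above 0, and for dynein the mean of 0.0038 was above 0 while median and test were below.

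Adhesion genes showed no shift as lists. Integrins and focal adhesion genes had a median of 0.01 (adjusted p 0.914), with the actin-binding gene Nexn at 0.35 ± 0.08, Lims2 at 0.29 ± 0.07 and Tgfb1i1 at -0.47 ± 0.11. Connexins, pannexins and tight junction genes had a median of -0.0033 (adjusted p 0.216), with the vascular connexin gene Gja5 at 0.24 ± 0.07, Cldn12 at -0.24 ± 0.07 and Jam3 at -0.24 ± 0.10. Without replicate 1 the latter list passed, at -0.07 with an adjusted p of 0.0447.

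Neuropeptide genes of the hypothalamus were higher in females as a list. Of 56 measured, 44 had a ratio above 0, 8 of them at an unadjusted p under 0.05, and the median was 0.23. Gnrh1, the releasing hormone at the head of the reproductive axis, stood at 0.99 ± 0.20 and above 0 on 4 of 4 arrays, or 0.67, 1.23, 1.52 and 0.53. Its upstream regulators Kiss1 and Tac3 stood at 0.48 ± 0.09, above 0 on 4 of 4 arrays, and at 0.49 ± 0.09, above 0 on 3 of 4. Over the alternatives Kiss1 ranged from 0.38 to 1.54, Gnrh1 from 0.77 to 1.22 and Tac3 from 0.42 to 0.56. The list rose with an adjusted p of 0.00960 at the preset correlation, and its adjusted p was 0.814 with an estimated correlation. The median was 0.08 with an adjusted p of 0.344 without replicate 2 and 0.40 without replicate 4. Male replicate 2, the animal with the highest level of cortical, hippocampal and striatal markers, had a median neuropeptide level of -0.48, against -0.08 to 0.09 in the other males. As all females were in estrus, sex and cycle stage cannot be separated in any of these ratios.

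Genes known from mouse as sexually dimorphic in the hypothalamus had a median of 0.04 (adjusted p 0.783). Moxd1, a marker of a male-enlarged preoptic nucleus, stood at -0.33 ± 0.11 and was below 0 on 3 of 4 arrays. Nnat, an imprinted gene of neuronal growth, stood at 0.35 ± 0.11, with 0.07 ± 0.30 at its second probe. Sex steroid receptor, synthesis and target genes had a median of 0.03 (adjusted p 0.812). Hsd11b2, which inactivates glucocorticoids, stood at 0.63 ± 0.11 and above 0 on 4 of 4 arrays, Hsd17b12 at -0.75 ± 0.20 and below 0 on 4 of 4 arrays, and the receptor coactivator gene Ncoa3 at -0.22 ± 0.07.

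Immediate early genes, which neurons switch on within minutes of activity, were lower in females as a list. Of 39 measured, 29 had a ratio below 0, 6 of them at an unadjusted p under 0.05 against 0 above, and the median was -0.17. Ier2 stood at -0.86 ± 0.16 and Klf2 at -0.43 ± 0.09, both below 0 on 4 of 4 arrays, and Dusp1 at -0.67 ± 0.15. The list fell with an adjusted p of 3.1e-04 at the preset correlation, and its adjusted p was 0.814 with an estimated correlation. Its median was -0.05 without replicate 2, where the list still passed at the preset correlation. The animals of replicate 2 had the highest median level of the list in their sex, 0.08 in the female and 0.12 in the male. They also had the highest level of cortical, hippocampal and striatal markers in their sex, 0.39 and 1.29.

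Circadian clock genes had a median of 0.0057 (adjusted p 0.338), with Nr1d1 at -0.30 ± 0.06, Cry1 at 0.28 ± 0.07 and Tef at -0.32 ± 0.10. Glucocorticoid target and stress genes had a median of 0.0032 (adjusted p 0.914), with Sult1a1 at 0.50 ± 0.07, Angptl4 at 0.44 ± 0.08 and Klf9 at -0.44 ± 0.15. In both lists the test and the mean, at -0.04 and -0.0099, were below 0, and for all X-linked genes the test also pointed down while the median was above 0.

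Oligodendrocyte and myelin genes were lower in females. Of 32 measured, 28 had a ratio below 0, and the median was -0.14. Gpr37 stood at -0.59 ± 0.15 and Ermn at -0.26 ± 0.07, both below 0 on 4 of 4 arrays. The list fell with an adjusted p of 4.5e-05 at the preset correlation, and its adjusted p was 0.814 with an estimated correlation. Its median was -0.08 without replicate 3. Neuron markers also fell at the preset correlation, with a median of -0.14, an adjusted p of 0.0200 and 24 of 34 below 0, and their adjusted p was 0.814 with an estimated correlation. Elavl3 stood at -0.34 ± 0.11 and Gabra2 at -0.25 ± 0.08. Without replicate 2 the median of the neuron markers was -0.00022 and their adjusted p 0.308, and without replicate 4 the median was -0.21. Male replicate 2, which also had the highest level of cortical, hippocampal and striatal markers, had a median neuron marker level of 0.24, against -0.06 to -0.0012 in the other males.

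Meningeal and fibroblast markers, genes of the membranes around the brain, were higher in females. All 23 measured had a ratio above 0, 9 of them at an unadjusted p under 0.05, and the median was 0.39. Slc47a1 belongs to this list and passed when adjusted over the list alone, the 1 gene to do so, at 0.0129. The matrix gene Ogn stood at 1.06 ± 0.19, with -0.76 and -0.59 on arrays 1 and 3 and 3.33 and 2.27 on arrays 2 and 4, and Asgr1 stood at 0.34 ± 0.09. The list rose with an adjusted p of 3.4e-07 at the preset correlation, and its adjusted p was 0.814 with an estimated correlation of 0.67. Its median was 0.21 without replicate 2 and 0.66 without replicate 4, and on the 4 arrays as measured it was -0.11, 1.38, -0.45 and 0.55.

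Cortical, hippocampal and striatal markers, genes of neighbouring forebrain regions, were lower in females. Of 25 measured, 18 had a ratio below 0, and the median was -0.33. Neurod6, a transcription factor gene of cortical and hippocampal neurons, stood at -0.96 ± 0.32, Lhx2 at -1.06 ± 0.29 and Cux2 at -0.26 ± 0.06, each below 0 on 4 of 4 arrays. The list fell with an adjusted p of 0.00111 at the preset correlation, and its adjusted p was 0.814 with an estimated correlation of 0.39. On the 4 arrays as measured its median was -0.14, -1.23, 0.10 and -0.04. The median was -0.0091 with an adjusted p of 0.377 without replicate 2 and -0.67 without replicate 4.

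The remaining cell types and neighbouring tissues did not pass. Astrocyte and tanycyte markers had a median of -0.06 (adjusted p 0.112), with the glial filament gene Gfap at -0.39 ± 0.12 and below 0 on 4 of 4 arrays. Mlc1 stood at -0.65 ± 0.21 and Sox9 at 0.20 ± 0.07, with 0.01 at the second probe of Sox9. Microglia and immune markers had a median of 0.15 (adjusted p 0.0886), with Lyz2 at 0.34 ± 0.09 and Cd14 at 0.24 ± 0.07, both above 0 on 4 of 4 arrays, and RT1-Bb at 0.46 ± 0.14, whose second probe read -1.42. Endothelial and mural markers had a median of 0.07 (adjusted p 0.183), with Des at 0.62 ± 0.16 and Tagln at 0.51 ± 0.16. Ependymal and choroid plexus markers had a median of -0.05 (adjusted p 0.447), with Tmem212 at 0.33 ± 0.09. Ttr, the most abundant transcript of choroid plexus, read 1.26, -2.69, -1.31 and -4.42 on arrays 1 to 4.

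Blood markers had a median of 0.07 (adjusted p 0.914), with the haemoglobin gene Hbb at 0.34 ± 0.52, Slc4a1 at -0.17 ± 0.14 and Retnlg at 0.04 ± 0.06. Pituitary markers had a median of 0.16 (adjusted p 0.111). Growth hormone, Gh1, stood at 0.63 ± 0.22, was well above background in 2 of 4 males and lay between 0.35 and 2.36 over the alternatives. Drd2 stood at 0.44 ± 0.18, with 0.07 at its second probe, and Gal at 0.79 ± 0.47, with 2.87 on array 2. Thalamic markers had a median of 0.09 (adjusted p 0.768), with Ptpn3 at -0.60 ± 0.15, Synpo2 at 0.19 ± 0.07 and Amotl1 at 0.16 ± 0.06. Other scalings brought pituitary markers past the threshold, with an adjusted p of 0.0146 after median centring, 0.0184 in the log ratios of the scanner software, 0.0325 without background correction and 0.0367 without the dye term. Median centring did so for microglia and immune markers (0.13, adjusted p 0.0125). Leaving out a replicate brought some of these lists past the threshold at the preset correlation. Without replicate 2 they were astrocyte and tanycyte markers (-0.11, adjusted p 8.1e-04), ependymal and choroid plexus markers (-0.20, adjusted p 1.7e-04) and blood markers (-0.32, adjusted p 0.00116). Without replicate 3 they were microglia and immune (0.19, adjusted p 0.00356), endothelial and mural (0.12, adjusted p 0.00178) and pituitary markers (0.14, adjusted p 0.0485). Without replicate 4 they were blood (0.43, adjusted p 0.0153), microglia and immune (0.17, adjusted p 0.0153) and pituitary markers (0.33, adjusted p 0.00130).

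Ribosomal protein genes were higher in females. Of 77 measured, 73 had a ratio above 0, and the median was 0.17. Rpl37a stood at 0.34 ± 0.07 and Rpl10l at 0.74 ± 0.16, both above 0 on 4 of 4 arrays, and Rpl35a at 0.33 ± 0.10. The other probes of Rpl37a read 0.17 and -0.10. The list rose with an adjusted p of 1.9e-08 at the preset correlation, and its adjusted p was 0.814 with an estimated correlation of 0.56. The median was 0.07 without replicate 2 and 0.26 without replicate 4, and male replicate 2 had a median level of -0.22, against -0.07 to -0.01 in the other males. Oxidative phosphorylation genes had a median of 0.06 (adjusted p 0.280), with 56 of 77 above 0, Ndufs7 at 0.29 ± 0.09, Ndufa12 at 0.25 ± 0.10 and Ndufa7 at -0.45 ± 0.19.

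In all, 9 of 33 lists passed with camera at the preset correlation, 4 higher and 5 lower in females. Leaving out a replicate kept the call at the preset for the cilia, immediate early, oligodendrocyte, meningeal and ribosomal lists. The preset correlation was 0.01, while the estimate for these 9 lists was -0.02 for immediate early genes and 0.10 to 0.67 for the others. Where genes of a list vary together more than the preset, its p-values at the preset are too small. With an estimated correlation 0 of 33 passed, with 0.814 as the lowest adjusted p and an unadjusted p under 0.05 for immediate early genes alone, at 0.0410. That test had little power on 4 arrays. It missed the list moved as a whole in the simulation, at an adjusted p of 0.434. Immediate early genes, whose estimate lay below the preset, did not pass it either. Its result therefore neither backs the 9 calls nor counts against them. With fry, which asks whether a list's own genes move one way on balance, 0 of 33 passed and the lowest adjusted p was 0.726, although intermediate filaments (0.0384) and immediate early genes (0.0446) had an unadjusted p under 0.05.

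**Figure D3:**
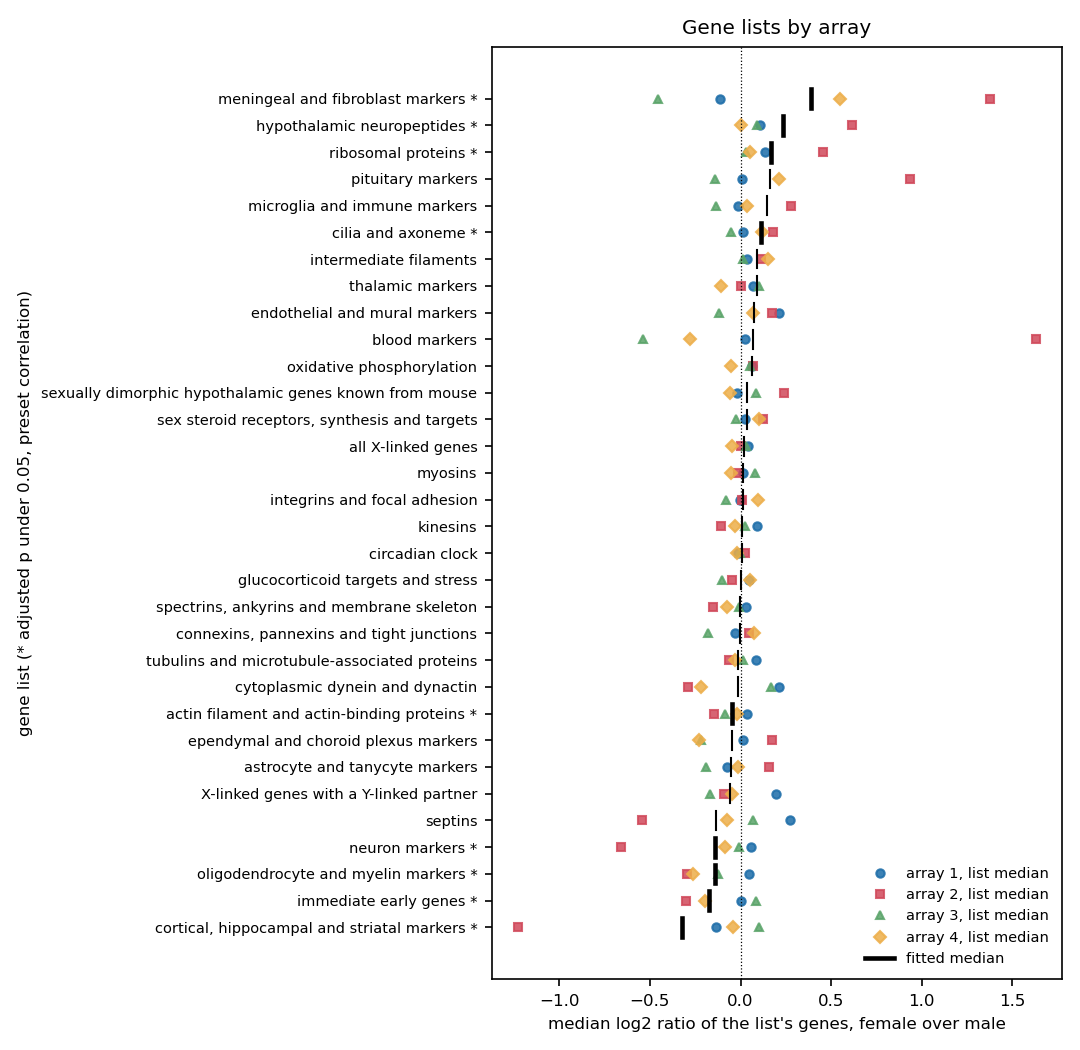
Median log2 ratio of female over male (horizontal axis) for 32 of the gene lists; points are the medians on each of the 4 arrays, black lines the fitted medians, thick and starred where the adjusted p was under 0.05 at the preset correlation. Array 2 lies farthest from 0 for the meningeal (1.38), blood (1.63) and cortical (-1.23) markers.

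**Figure D4:**
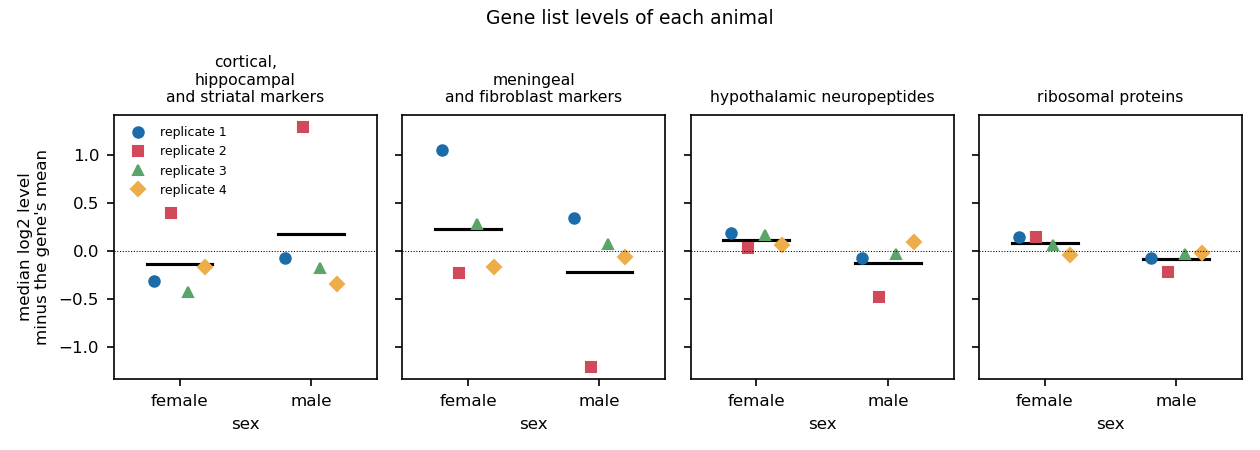
Median log2 level of a list's genes in each of the 8 animals relative to each gene's mean over the animals, after removal of the dye effect (vertical axis), for 4 lists; points are animals by replicate number and black lines the mean of each sex. Male replicate 2 lies at 1.29 for the cortical, hippocampal and striatal markers and at -1.21 for the meningeal and fibroblast markers. Female replicate 2 lies at 0.39 for the cortical, hippocampal and striatal markers and at -0.23 for the meningeal and fibroblast markers.

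Spread between animals was compared because the study asked for features of the cytoskeletal transcriptome beyond the mean. The median over 14485 genes of the log2 ratio of female to male standard deviation was -0.25, with median standard deviations of 0.129 in females and 0.149 in males, and 62.4% of genes varied more between males. An exact permutation over 35 splits of the animals gave a two-sided p of 0.629, where the smallest possible is 0.0286, and the 8 exchanges of sex within arrays gave an exact p of 0.375, where the smallest possible is 0.125. Over 588 cytoskeletal genes the ratio was -0.22, with an exact permutation p of 0.886. The adjusted p of both sets was 0.886. The sign turned without replicate 2, at 0.07 for all genes and 0.15 for cytoskeletal genes, and without replicate 4, at 0.02 and 0.04. Median absolute deviation from the group mean over genes was 0.156 in male replicate 2 and 0.0693 to 0.106 in the other 7 animals.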

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

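The counts over other splits of the samples were planned before the data were examined; the tests of the cortical markers and of the genes passing without replicate 4 were chosen only after those results were seen.

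Within each sex, the highest or lowest of the 4 animals was compared with the other 3 by Dixon's test for each named gene and list, on log2 levels with the dye effect removed. It set apart 1 animal in 11 of 286 groups, or 3.85%, and chance gives about 1 in 20 groups, or 14.3 here. Male replicate 2 stood apart in Neurod6, a cortical and hippocampal gene, at 13.86 against 8.18 to 9.08 in the other males, in Ptpn3 at 9.20 against 7.74 to 7.82, and in Ing3 at 8.67 against 9.29 to 9.41. It also stood apart in the median level of the cortical, hippocampal and striatal markers, 1.29 against -0.34 to -0.07, and of the septins, 0.27 against -0.07 to -0.01, both relative to each gene's mean. Female replicate 2 was not set apart by the test, but its level of the cortical, hippocampal and striatal markers was 0.39, against -0.43 to -0.17 in the other females. Male replicate 4 stood apart in Cux2 at 11.85 against 12.39 to 12.47 and in Kif26b at 7.37 against 7.27 to 7.28. Among females, Angptl4 was 10.76 in replicate 4 against 10.60 to 10.62, Mrpl18 was 11.97 in replicate 3 against 12.25 to 12.27, and in replicate 1 Nr1d1 was 10.21 against 10.04 to 10.05 and the thalamic markers were -0.063 against 0.028 to 0.040.

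Cortical, hippocampal and striatal markers were lower in females, with a median log2 ratio of -0.33, and on array 2 of -1.23. Little of a bend of the ratios with brightness was left on array 2, where 2268 genes of matched brightness had a median of -0.016. Loess within arrays sets such a median near 0, so this is no independent test of a bend. The replicate 2 pair alone may account for the shift, since the median without it was -0.0091. Less telencephalic tissue in the female than in the male sample of replicate 2 stays open: 20 of the 25 members were lower in the female on that array, against 17, 9 and 14 on arrays 1, 3 and 4, but any cause of a low list there would give such a count. A difference between the sexes stays open as untested.

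Without replicate 4, 1132 genes passed, while 0 passed with limma on all 4 arrays, where 1244 had an unadjusted p under 0.05. On array 4 the Y-linked gene Ube1y1 was well above background in the male and not in the female, as on the other 3 arrays, with a log2 ratio of -0.53, which goes against an exchange of the sexes there, though 1 gene this dim does not exclude it. On arrays 1 to 3 the ratio of Ube1y1 was -0.43, -0.03 and -0.67. Replicate 2 weighed on the calls by design. Without replicate 4, array 2 was the only array with females in Cy5, so its ratios entered each estimate unchecked by another array. Leaving out replicate 2 in place of replicate 4 kept the sign for 74.9% of these genes. Both estimates hold arrays 1 and 3, so a shared sign is partly built in. Without replicate 2 the sign was kept with an unadjusted p under 0.05 for 20.2% of the genes. Their median absolute log2 ratio was then 0.11 against 0.65. The genes were picked without replicate 4, so smaller ratios elsewhere also follow from that choice. In both fits the residual spread rests on arrays 1 and 3, and leaving out replicate 2 gave 0 passing genes and 1182 genes at an unadjusted p under 0.05, so that spread alone does not account for the calls. The fits differ in holding array 2 or array 4, so the calls turn on the ratios of array 2 in place of array 4. A difference between the sexes stays open as untested.

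Of the 8 ways to label the sexes within arrays, 7 could be fitted, the real one included, too few for a share under 0.05. Genes passing numbered 0 for the real labels and at most 1022 for the others, so 7 of 7 are as large by construction, the real one counted here and below. At an unadjusted p under 0.05 the real labels gave 1244 genes and the highest other 3960, with 2 of 7 as large; for cytoskeletal genes these were 69 and 189, with 2 of 7 as large. For lists at the preset correlation they were 9 and 14, with 3 of 7 as large. Exchanging replicate 4 alone gave the counts of 1022 and 3960. There arrays 1, 3 and 4 measure 1 contrast and array 2 is fitted exactly, so these counts cannot be set against the real ones. The labelings that keep sex balanced over the dyes are the real one and the exchanges of replicates 2 and 3 and of 3 and 4. They gave 1244, 111 and 463 genes at an unadjusted p under 0.05 and 9, 10 and 8 lists, too few labelings to weigh chance.

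Over the 34 of 35 splits of the animals that could be fitted without the array as block, the real one included, chance could not be excluded for the counts at an unadjusted p and of lists. Genes passing numbered 0 for the real split and 75 for the highest other, so 34 of 34 are as large by construction. At an unadjusted p under 0.05 these were 1091 and 2538 genes, with 6 of 34 as large, and 52 and 133 cytoskeletal genes, with 8 of 34. For lists they were 9 and 15, with 11 of 34. Among the 7 splits that part the animals of all 4 arrays as sex does, the real one gave 1091 genes and the others 94 to 2189, with 2 of 7 as large.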

How the results depend on the processing

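No test here was chosen only after the result was seen. Genes differing between sexes numbered 0 with limma under each alternative except leaving out a replicate, where it ranged from 0 to 1132 (probes differing between sexes 0 to 1546, cytoskeletal genes differing between sexes 0 to 60, adjusted over the list alone 0 to 103); the highest values came without replicate 4. Under unadjusted p with 1.5-fold it was 132 genes and 11 cytoskeletal genes. The 1244 genes at an unadjusted p under 0.05 became 405 without the dye term, 777 after median centring and 303 to 4546 leaving out a replicate, and the 69 cytoskeletal genes at an unadjusted p under 0.05 became 20 without the dye term and 30 to 223 leaving out a replicate. Without the array as block these were 1091 and 52, and 9 lists passed. The effect of the dye term follows from the residual variance it removes; the cause of the others was not tested.

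Lists past the threshold numbered 9, and 0 with an estimated correlation or with fry. With an estimated correlation the list moved in the simulation did not pass either, at an adjusted p of 0.434. Of 462 list values under alternatives, 396 kept their direction and side of the threshold, 24 lost the threshold, 16 passed it and 26 turned direction, for lists that did not pass with all arrays; blood markers passed in the turned direction without replicate 2 (-0.32). Direction turned under fry for kinesins (0.0063), X-linked genes with a Y-linked partner (-0.061), stress genes (0.0032) and all X-linked genes (0.021); without the block for kinesins (0.0063) and integrins (0.013); after median centring for kinesins (0.013); with no filter for stress genes (0.0032); with all channels well above background for kinesins (0.044); and with the mean of probes for stress genes (0.015). Direction is that of the test, which compares a list with the other genes, so the median can keep its sign.

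Leaving out a replicate turned the test's direction for these lists, with medians from -0.021 to 0.045 for kinesins, -0.064 to 0.041 for dynein, 0.0059 to 0.019 for myosins, -0.017 to 0.044 for integrins, -0.057 to 0.012 for X-linked genes with a Y-linked partner, 0.0082 to 0.031 for all X-linked genes, 0.015 to 0.082 for sexually dimorphic genes, 0.0092 to 0.054 for stress genes, -0.32 to 0.43 for blood, -0.20 to 0.049 for ependymal, 0.0053 to 0.33 for pituitary and 0.0076 to 0.12 for oxidative phosphorylation. Of 1821 named-gene values, 1787 kept direction and side, 27 passed the threshold, each without replicate 4, and 7 turned: Med14 to 0.0014 after median centring, RT1-Bb to -0.48 with the mean of probes, and, leaving out a replicate, Hbb (-0.37 to 1.06), Rbmx (-0.18 to 0.044), Sry (-0.034 to 0.068) and Usp9x (-0.41 to 0.11). The ratio of spread between animals ranged from -0.39 to 0.071 for all genes and -0.43 to 0.15 for cytoskeletal genes leaving out a replicate. The cause was not tested. Leaving out saturated spots moved nothing, as there were 0. Signal above background was lower in Cy5, 148 to 272, than in Cy3, 502 to 530.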

Other observations

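The list of genes and both tests below were chosen only after the result was seen.

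Genes that escape X inactivation in mouse are read from both X chromosomes in females. Of 7 such genes listed, 4 were measured, and their log2 ratios were 0.61 ± 0.09 for Eif2s3, 0.50 ± 0.08 for Pbdc1, 0.33 ± 0.07 for Ddx3x and 0.12 ± 0.11 for Utp14a. None of the 4 passed the threshold. Their median was 0.42, against 0.02 for the 471 X-linked genes measured, of which 256 were above 0. The list was drawn up after Eif2s3 and Ddx3x had been seen above 0, so this median does not test a shift shared by all X-linked genes. A direction decided by 1 probe per gene stays open as well, since 1 of the 3 other probes, that of Ddx3x, had the opposite sign, both probes of Utp14a lay near 0 and Pbdc1 had no other probe. Escape from X inactivation may underlie the ratio of 0.63 at the second probe of Eif2s3 and the median of 0.42, as a hypothesis that these data leave untested. Eif2s3 and Pbdc1 differed with the dye, at 1.503 and 0.17 on array 1 and -0.37 and 1.02 on array 2.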
